A study of Mus musculus with 8 samples.

How the data were processed

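Poly(A) RNA of BMiFLT3 (15-3) cells infected with a BFP or a Klf2 retrovirus was sequenced on an Illumina HiSeq instrument, per the labels' protocols. These protocols name 2 library kits without saying which library was made with which, so a difference in kit between the groups is not excluded. CASAVA 1.8.2 and the genome build mm10 are named in the submitters' processing notes. The aligner, the counting program, the gene annotation, and whether strand was used in counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene may not be separated.

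The authors deposited 1 table of 38918 gene rows. Per the file headers, the authors' counts for each lane are all exon reads, uniquely placed exon reads, all gene reads and reads across exon junctions. The deposited RPKM values are exon reads scaled by exon length and by the total gene reads of a lane, which was checked by recomputing them from the deposited columns (largest difference 0.0258 RPKM). The deposited median coverage of each gene was used in the closing section, and the authors' deposited fold, a signed score per gene, is the ratio of mean RPKM between the groups. Counts of all exon reads, the reads behind the RPKM, are the main values. They include reads with several placements: 83.2% of exon reads in BFP and 83.3% in Klf2 were uniquely placed. Of the 881 genes past the rule below, 207 (23.5%) had under 90% uniquely placed reads, and such genes are uncertain where they share sequence with a copy. Among named genes under 90%, the fold on uniquely placed reads lay on the other side of the 2-fold limit for Rpl13, Txnip and Acta2, and on the other side of 1 for Rpl28.

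The 4 samples of a group have titles that differ in a lane name and share a description. Chi-square of the lane counts per degree of freedom was 1.21 in both groups on all exon reads, and 1.02 (BFP) and 1.03 (Klf2) on uniquely placed reads, below the limit of 1.5 fixed before the data were examined. In simulated data it was 1 for lanes of a single library and 20.3 with 20% of variation added between lanes. The lanes of a group thus differed by about sampling noise, were summed, and were counted as 1 sample, n = 1 per group. The libraries were similar in the share of gene reads outside exons (15.2% and 15.1%), of exon reads on junctions (21.9% and 22.4%) and of mitochondrial reads (6.18% and 6.12%). A count of 0 allows up to 0.0996 CPM in BFP and 0.0973 CPM in Klf2, from 3 reads over the total exon reads, before TMM scaling. Reads were counted without molecular identifiers, so intervals of reads and this limit cover counting error only.

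CPM was scaled with TMM in edgeR 4.0.16 under R 4.3.3, with factors of 1.03 for BFP and 0.969 for Klf2, a shift of 0.09 on the log2 scale. No test of the conditions was possible with 1 library per group. A gene passed the rule when its CPM ratio was at least 2 in either direction and the exact (Clopper-Pearson) 95% interval of the ratio, conditional on the summed reads, excluded 1, among genes with at least 1 CPM in either library. For a check, 2 libraries were simulated with counting error only around the BFP counts, at the read totals of the BFP and Klf2 libraries. With 10795 genes tested, the rule took 0 of 50 genes with a true fold of 1.5, 49 of 50 at 2.5 and 49 of 50 at 3. It took 50 of 50 at 4 and 7 of 10595 unchanged genes. The simulation held no variation between cultures or preparations, so it gives no rate of false calls for these data.

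The 27 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes Klf2, the 10 genes furthest in each direction on the log2(CPM + 1) scale among those past the rule, leaving out provisional symbols and immunoglobulin variable segments, and up to 4 members of each list with the largest log2 difference, those past the rule first. The provisional or variable genes left unnamed were 42 of the higher and 78 of the lower genes. List genes outside this rule are named only where the text says so, and a housekeeping gene that the rule takes is not reported here. For each list with at least 5 measured members, the median log2 difference is given with its percentile among 10000 random lists of the same size drawn from 20 bins of expression, as a description of these libraries. Random lists draw genes independently, so about 5% of lists would fall outside the central 95% by chance only if list genes varied independently. In data simulated with counting error only and no gene changed, 1 of 25 did. Genes that vary together between cultures can bring more lists outside, so 5% is not the chance rate for these lists. Of the list genes, 7 did not match a row of the table. Some lists share members, such as Btg2, Bbc3, Klf2 and S1pr1.

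Coordinates are those of the table, in mm10. Of 35529 symbols also present in the GENCODE annotation, 99.8% overlapped it by position, and transcript GC content taken from that annotation was available for 94.2% of the genes tested and 93.4% of those past the rule. The alternatives were DESeq2 1.42.0 size factors, total counts, other floors, folds and pseudocounts, and leaving out each lane. Uniquely placed reads, all gene reads, mean RPKM, centring by transcript GC or by expression, and scaling on the lowest or highest of 5 groups of genes by expression were added after the data had been seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.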

Results

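RNA was measured by poly(A) RNA sequencing in BMiFLT3 (15-3) cells, mouse pro-B cells from a B-cell precursor leukaemia line. The cells had been infected with a control retrovirus for blue fluorescent protein (BFP) or with one for Klf2. Klf2 is a zinc-finger transcription factor of the Krüppel-like family. The file headers carry BFP in the column names of both groups, so BFP may be on both constructs. The question set by the design is which genes differ when Klf2 is overexpressed in these B-cell progenitors. The 8 deposited samples are 4 sequencing lanes of each construct. The lanes of a construct differed by about sampling noise and were counted as 1 sample, so each group holds 1 library. The BFP library held 30133978 exon reads, between 7506567 and 7588695 per lane, and the Klf2 library 30835450, between 7682298 and 7741626 per lane. With 1 library per group, no difference below has a replicate check and no p-value is given. Every interval is a 95% exact interval. Intervals of reads cover counting error only, and intervals of shares of genes treat genes as independent. Fold means the Klf2 library over the BFP library, in CPM, reads of a gene scaled to library size with TMM, and log2 differences are on the log2(CPM + 1) scale.

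Klf2 itself was 11.1-fold higher in the Klf2 library (9.93 to 12.6), at 113 CPM from 3364 reads against 10.1 CPM from 314 reads. The gene lies on chromosome 8, 72319033 to 72321656 (mm10), with 3 exons and an exon length of 1847 bases, and 100% of its exon reads were uniquely placed. The deposited RPKM of Klf2 was between 4.30 and 5.38 in the 4 BFP lanes and between 48.7 and 51.0 in the 4 Klf2 lanes. The authors' deposited table gives a fold of 10.5 for the mean RPKM of this gene.

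**Figure D1:**
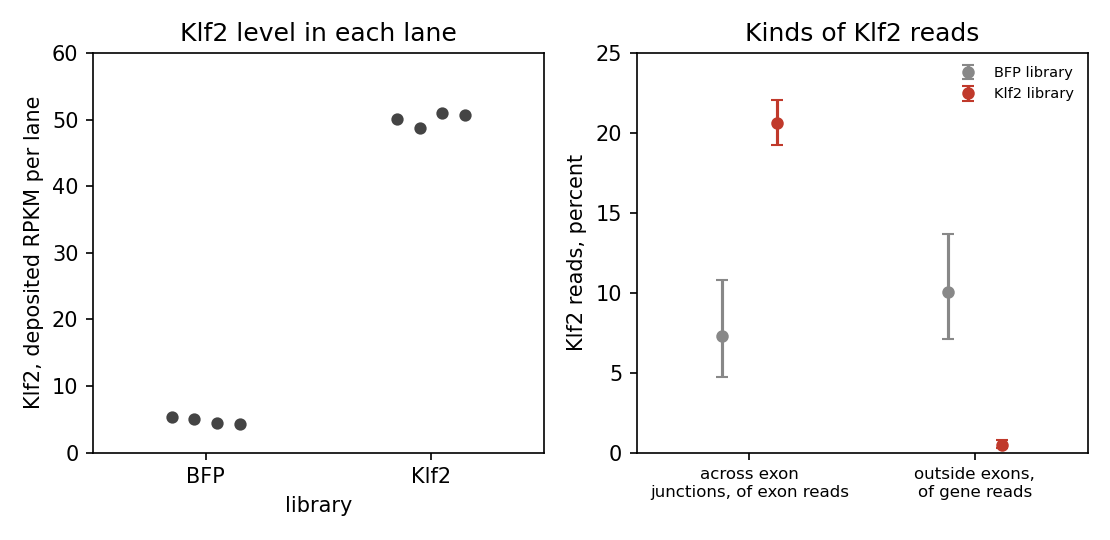
Left, the deposited RPKM of Klf2 in each lane of the BFP and Klf2 libraries (linear axis from 0, 1 point per lane), between 4.30 and 5.38 in BFP and between 48.7 and 51.0 in Klf2. Right, the percent of Klf2 exon reads that span an exon junction and the percent of Klf2 gene reads outside exons, summed over lanes, with exact 95% intervals; junction reads were 7.32% in BFP and 20.6% in Klf2.

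With TMM scaling, more genes were lower than higher in the Klf2 library. Of 10850 genes with at least 1 CPM in either library, 266 were at least 2-fold higher and 615 at least 2-fold lower, with the interval of the ratio excluding 1. Genes of DNA replication, mitosis and ribosome biogenesis were higher as groups, and NF-kB pathway and inflammatory genes and FOXO target genes were lower as groups, as were interferon-stimulated genes with the floor of 1 CPM but not with a floor of 10 CPM. The remaining 9969 genes did not pass the rule, and the median log2 difference over all genes was -0.01. With the deposited RPKM, whose scaling is the total reads of a lane, the split was 128 higher and 559 lower. That setting also had a floor of 1 RPKM in place of 1 CPM and used no interval, so it differs in more than scaling. Over 5 equal groups of genes by mean CPM, the median log2 ratio ran from -0.20 in the lowest group to 0.17 in the highest. Scaling on the lowest group turned the split to 543 higher and 419 lower, and scaling on the highest gave 173 and 881. Lanes 1 and 2 of the same library set against lanes 3 and 4 gave 61 of 10819 genes past the same rule in BFP and 67 of 10651 in Klf2. On uniquely placed reads these were 37 of 10524 and 28 of 10367. Lanes of 1 library hold no variation between cultures or preparations, so these counts give no rate of false calls between the groups.

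The genes furthest above the BFP library, after Klf2, were Cplx2, Cpne2, Slc5a9, Dlg2, Blk, 3 segments of the T-cell receptor gamma locus and Ddc. Cplx2, a complexin of vesicle exocytosis (chromosome 13, 54371349 to 54383917), was at 46.3 against 7.85 CPM, a fold of 5.90 (5.14 to 6.79). Cpne2, a copine (chromosome 8, 94532990 to 94570529), was at 140 against 29.1 CPM, a fold of 4.83 (4.49 to 5.19). Slc5a9, a sodium-coupled sugar transporter (chromosome 4, 111875375 to 111902918), was at 10.2 against 1.38 CPM, a fold of 7.36 (5.33 to 10.4). Dlg2, a synaptic scaffold protein (chromosome 7, 91090706 to 92447003), had 129 reads against 6, a fold of 22.4 (10.003 to 62.1). Blk, a Src-family kinase of B cells (chromosome 14, 63372837 to 63417187), was 4.996-fold higher (4.23 to 5.93). On chromosome 13, Tcrg-V4 (19184981 to 19185501) was 4.35-fold, Tcrg-C1 (19214103 to 19216618) 4.62-fold and Tcrg-C2 (19305060 to 19307551) 4.48-fold higher. The C segments share reads with near copies, with 68.6% of Tcrg-C1 and 84.5% of Tcrg-C2 reads uniquely placed, and on uniquely placed reads the folds were 4.60 and 4.35. Ddc, which makes dopamine and serotonin from their amino acid precursors (chromosome 11, 11814101 to 11898144), was at 14.5 against 2.83 CPM.

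The genes furthest below were Ostn, Bmf, Angptl6, Ccl3, Shank1, Trim66, Faim3, Oas2, Atf3 and Ccl4. Ostn, which encodes osteocrin (chromosome 16, 27307489 to 27351212), was at 1.54 CPM in the Klf2 library against 26.9 CPM in BFP, a ratio of 0.0571 (0.0415 to 0.0769). Bmf, a pro-apoptotic BH3-only member of the BCL2 family (chromosome 2, 118528757 to 118549687), was at 4.99 against 57.7 CPM, a ratio of 0.0864 (0.0726 to 0.102). The chemokine gene Ccl3 (chromosome 11, 83647844 to 83649355) was at 48.1 against 398 CPM, a ratio of 0.121 (0.114 to 0.128), and its neighbour Ccl4 (83662584 to 83664683) had 20 reads against 302. Angptl6 (chromosome 9, 20873809 to 20879727) was at 3.35 against 34.7 CPM and Shank1 (chromosome 7, 44310253 to 44358351) at 1.87 against 21.1 CPM. Trim66 (chromosome 7, 109449006 to 109508134) was at 3.75 against 34.0 CPM. Faim3, an IgM Fc receptor (chromosome 1, 130865669 to 130880790), was at 8.37 against 64.0 CPM. Oas2, an interferon-induced oligoadenylate synthetase (chromosome 5, 120730333 to 120749853), had 37 reads against 451. Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191183340), had 69 reads against 635.

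**Figure D2:**
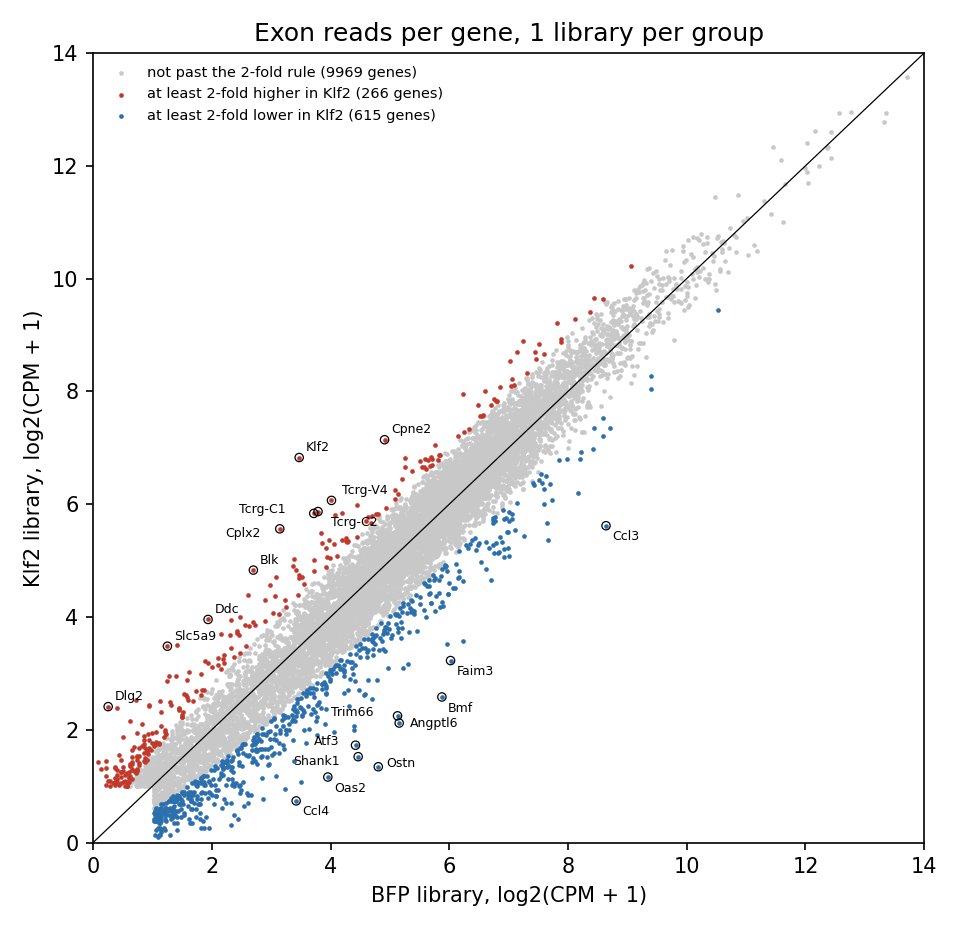
Each point is a gene with at least 1 CPM in either library, placed by its log2(CPM + 1) in the BFP library (x) and in the Klf2 library (y), with the line of equal values. The 266 genes at least 2-fold higher are red, the 615 at least 2-fold lower are blue, and the 10 furthest on each side are circled and named.

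Genes of DNA replication and mitosis were higher almost throughout. For DNA replication, 29 of 30 measured genes had an interval above 1 and 7 were at least 2-fold higher, none at least 2-fold lower. The median log2 difference was 0.72, at the 100th percentile of 10000 random lists matched on expression. At this depth an interval can exclude 1 at a small fold. Of 16 housekeeping genes, 11 had an interval above 1 and 5 had one below. Counts of intervals were not set against all genes for any list, so the percentile carries the comparison. Rrm1, a subunit of ribonucleotide reductase, was at 487 against 235 CPM, and the replication-licensing gene Cdc6 at 154 against 74.9 CPM. Mcm10 was 2.03-fold (1.94 to 2.12) and the chromatin assembly gene Chaf1b 2.09-fold higher (1.97 to 2.21). For mitosis, 30 of 30 genes had an interval above 1 and 4 were at least 2-fold higher, with a median of 0.82, again at the 100th percentile. The 4 were Hmmr at 2.10-fold, Kif20a at 2.07-fold, Cdc20 at 2.05-fold and Cdk1 at 2.01-fold. Among 27 regulators of G1 and quiescence, 4 were at least 2-fold higher and 6 at least 2-fold lower, and the list median of -0.01 lay inside the random lists. Cyclin genes Ccnd3 (1193 against 531 CPM) and Ccne2 (75.6 against 32.9 CPM) were higher, as were Ccne1 and E2f2 (148 against 69.8 and 228 against 109 CPM, named after their values were seen), while the anti-proliferative genes Btg1 (38.0 against 105 CPM) and Btg2 (23.2 against 62.8 CPM) were lower.

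Genes of the NF-kB pathway and inflammatory list were lower in the Klf2 library. Of 28 measured genes of the NF-kB pathway and inflammatory list, 13 were at least 2-fold lower and none at least 2-fold higher, and 23 had an interval below 1. The median of -0.79 lay below all 10000 random lists. Beside Ccl3, Ccl4 and Atf3, the list included Egr2, an immediate-early transcription factor, at 5.22 against 23.0 CPM. Interferon-stimulated genes showed the same direction: 15 of 31 were at least 2-fold lower and none at least 2-fold higher, with a median of -0.69, also below all random lists. With a floor of 10 CPM, which leaves 15 interferon-stimulated genes, their median was -0.30 and lay inside the random lists. Irf7, a transcription factor of the interferon response, had 28 reads against 260, Oasl2 17 against 151 and Oas3 16 against 109. The cytokine receptor and JAK-STAT list had 18 of 24 genes with an interval below 1 and a median of -0.24, at the 0.73 percentile. In that list Cish, a feedback inhibitor of STAT5 signalling, was at least 2-fold lower at 30.5 against 91.8 CPM, with 36.9% of its reads uniquely placed. Among 7 myeloid markers, Fcgr1, Tyrobp and Ccr2 were also at least 2-fold lower, and Mrc1 was at least 2-fold higher. Jak2 was at 18.3 against 32.4 CPM, Il10ra at 2.14 against 3.57 CPM and Stat5a at 55.3 against 38.6 CPM.

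Genes of cell migration and FOXO target genes were lower on balance. In the homing and adhesion list, 4 of 20 genes were at least 2-fold lower and none at least 2-fold higher, with a median of -0.37 at the 0.35 percentile. These were S1pr1, the sphingosine-1-phosphate receptor of lymphocyte egress, with 10 reads against 137, the chemokine receptor gene Ccr7 with 48 against 208, Rgs1 with 3 against 45, and the cannabinoid receptor gene Cnr2 with 71 against 148. The ratio of S1pr1 was 0.0760 (0.0356 to 0.144). With a floor of 10 CPM, which leaves 11 homing genes, the list median was -0.07 and lay inside the random lists. In the FOXO list, which holds Klf2 itself, 7 of 23 genes were at least 2-fold lower and 2 at least 2-fold higher, Klf2 and Txnip (111 against 51.1 CPM, named after its values were seen). Only 17.3% of Txnip reads were uniquely placed, and on those its fold was 1.87, under the rule. Its median of -0.59 lay below all random lists. Pik3ip1, an inhibitor of PI3-kinase, was at 17.3 against 58.6 CPM. The KLF family list, which also holds Klf2, had 3 of 15 genes at least 2-fold lower and a median of -0.41 at the 0.33 percentile; without lane 3 it was -0.18, inside the random lists. Klf6 was at 34.4 against 113 CPM, Klf3 at 6.49 against 19.2 CPM and Klf8 at 5.02 against 12.3 CPM. Of 6 measured endothelial KLF2 target genes none passed the rule, and the median of -0.12 lay inside the random lists. In that list Cxcr4 was at 130 against 211 CPM, Jam3 at 4.35 against 2.89 CPM, Klf4 at 1.71 against 2.60 CPM and Thbd at 38.7 against 49.9 CPM.

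Genes of apoptosis and the p53 response were lower where they passed the rule. Of 21 p53 target genes, 4 were at least 2-fold lower and none at least 2-fold higher, with a median of -0.29 at the 0.16 percentile. The other 17 did not pass the rule. Over the whole list, 15 intervals lay below 1 and 3 above. Trp53inp1 was at 32.5 against 120 CPM, Bbc3, which encodes the BH3-only protein PUMA, at 12.9 against 30.6 CPM, and the growth-arrest gene Gadd45a at 15.5 against 33.4 CPM. Of 13 BCL2 family genes, 3 were at least 2-fold lower, namely Bmf, Bbc3 and Bcl2l2, and the list median of -0.24 lay inside the random lists at the 4.66 percentile. Bcl2l2 had 31 reads against 98, of which 24.03% were uniquely placed, and Bcl2l11 was at 30.3 against 48.7 CPM.

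The B-lineage lists held genes on both sides. In the pre-B-cell receptor list, 2 of 22 genes were at least 2-fold higher, Blk and Prkcb (2.37-fold, 1.88 to 3.02), and 2 at least 2-fold lower, Rasgrp3 (2.88 against 15.7 CPM) and Fyn (125 against 343 CPM, with 59.6% of reads uniquely placed). The median of this list was 0.04, at the 22.6 percentile, and -0.05 with total-count scaling. Among 25 B-lineage transcription factors, Spib (62.2 against 20.8 CPM) and Id3 (13.4 against 5.21 CPM) were at least 2-fold higher, and Id2 (14.9 against 48.0 CPM) and Bcl6 (19 reads against 70) at least 2-fold lower. The median was -0.08, at the 2.92 percentile. Of 18 markers of later B-cell stages, the invariant chain gene Cd74 was at 10.9 against 73.9 CPM, a ratio of 0.148 (0.132 to 0.166), and Cd86 had 10 reads against 32. Cd38 was at least 2-fold higher with 37 reads against 12, while Sdc1 was at 25.9 against 15.4 CPM, and the list median was -0.06. Of 10 measured genes of V(D)J recombination, the DNA ligase gene Lig4 was 2.03-fold higher (1.81 to 2.28), and the median of 0.16 lay inside the random lists. Hmgb2 was at 770 against 402 CPM and Hmgb1 at 584 against 386 CPM, with 29.4% and 48.5% of reads uniquely placed, and Nhej1 was at 3.35 against 4.95 CPM.

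Ribosome biogenesis and respiratory chain genes were higher on balance, with none past the 2-fold rule, and glycolytic genes were lower on balance. In the MYC-linked ribosome biogenesis list, 29 of 30 genes had an interval above 1 and none passed the 2-fold rule, with a median of 0.61 at the 100th percentile. Nop58 had a fold of 1.76 (1.69 to 1.84), Pa2g4 of 1.79 (1.76 to 1.82), Nolc1 of 1.67 (1.64 to 1.71) and Nme1 of 1.85, the last with 13.0% of reads uniquely placed. For oxidative phosphorylation, 26 of 30 genes had an interval above 1, with a median of 0.37 at the 99.9 percentile. Ndufa4 had a fold of 1.64 (1.57 to 1.72), Ndufs1 of 1.56, Uqcrb of 1.81 and Cycs of 1.73, with 24.99% and 15.4% of reads uniquely placed for the last pair. For glycolysis, 13 of 21 genes had an interval below 1 and the median of -0.28 lay at the 0.02 percentile. Aldoa, the aldolase gene, was at 697 against 1471 CPM and was the list's only gene past the rule. Tpi1 was at 479 against 880 CPM, Hk1 at 20.3 against 36.8 CPM and Pgk1 at 388 against 634 CPM, with 2.12% of its reads uniquely placed.

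Cytosolic ribosomal protein genes had a median of -0.18, below all random lists, with 31 of 40 intervals below 1 and none past the 2-fold rule on all reads. Their reads are shared with many pseudogenes. On all reads Rpl18 had a ratio of 0.695, Rplp1 of 0.740 and Rpl13 of 1.84, with 10.04%, 47.4% and 25.1% of reads uniquely placed. On uniquely placed reads the ratios were 0.720, 0.750 and 2.74, the last above 2-fold. Rpl13 had only 221 reads against 125 with all placements, while Rpl18 had 21511 against 32226. The ratio of Rpl13 thus rests on few reads. Rpl28, with 2.90% of reads uniquely placed, had a ratio of 0.711 on all reads and of 1.17 on uniquely placed reads. The cholesterol and fatty acid synthesis list (28 genes, median 0.05) and the unfolded protein response and ATF4 list (27 genes, median 0.06) lay inside the random lists, and with total-count scaling both medians were below 0, at -0.04 and -0.03. In the first, the fatty acid elongase gene Elovl6 was 2.68-fold higher (2.57 to 2.80), Insig1 was at 57.9 against 89.2 CPM, Idi1 at 161 against 106 CPM and Acaca at 202 against 145 CPM. In the second, the pseudokinase gene Trib3 was at 49.8 against 198 CPM, Ddit3 at 34.9 against 70.4 CPM and Sesn2 at 85.3 against 130 CPM. None of 16 housekeeping genes passed the rule, and their median was 0.10. Tubb5 was at 1653 against 1035 CPM. Ppia had a fold of 1.78 on all reads and 1.17 on the 2.499% of its reads that were uniquely placed.

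Markers of other blood cells were mostly near or below the floor. Of 24 myeloid markers found in the table, 7 were measured. Of these, Fcgr1 (24 reads against 166), Tyrobp (21 against 112) and Ccr2 (45 against 110) were at least 2-fold lower, and Mrc1 (125 against 54) was at least 2-fold higher. The median of this list was -0.64, at the 1.79 percentile, and without lane 3 it was -0.54, inside the random lists, as it was in 3 other settings. Chosen after their values were seen, the abundant myeloid genes Lyz1, Lyz2, S100a8 and S100a9 together had 12 reads in the BFP library and 20 in the Klf2 library. Of 29 T and NK cell markers found, 10 were measured, 6 with an interval above 1 and 3 with an interval below 1. The list median was 0.54, at the 99.97 percentile. With a floor of 10 CPM, 2 genes of the T and NK list and 1 of the myeloid list remained. Neither list therefore had a percentile with that floor. The T-cell receptor kinase gene Lck (27.1 against 12.3 CPM), the adaptor gene Lat (8.50 against 3.54 CPM) and Thy1 (37 reads against 16) were at least 2-fold higher, and the NK receptor gene Klrd1 (3.18 against 8.20 CPM) at least 2-fold lower. Of the erythroid and megakaryocyte list, 2 genes were measured, Tal1 at 28.5 against 20.6 CPM and Itga2b at 1.54 against 2.22 CPM. Of the stromal list, 3 were measured, Thy1, Tagln at 3.31 against 4.02 CPM and Acta2 at 1.77 against 2.35 CPM. Acta2 had a ratio of 0.755 on all reads and 0.474 on uniquely placed reads.

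**Figure D3:**
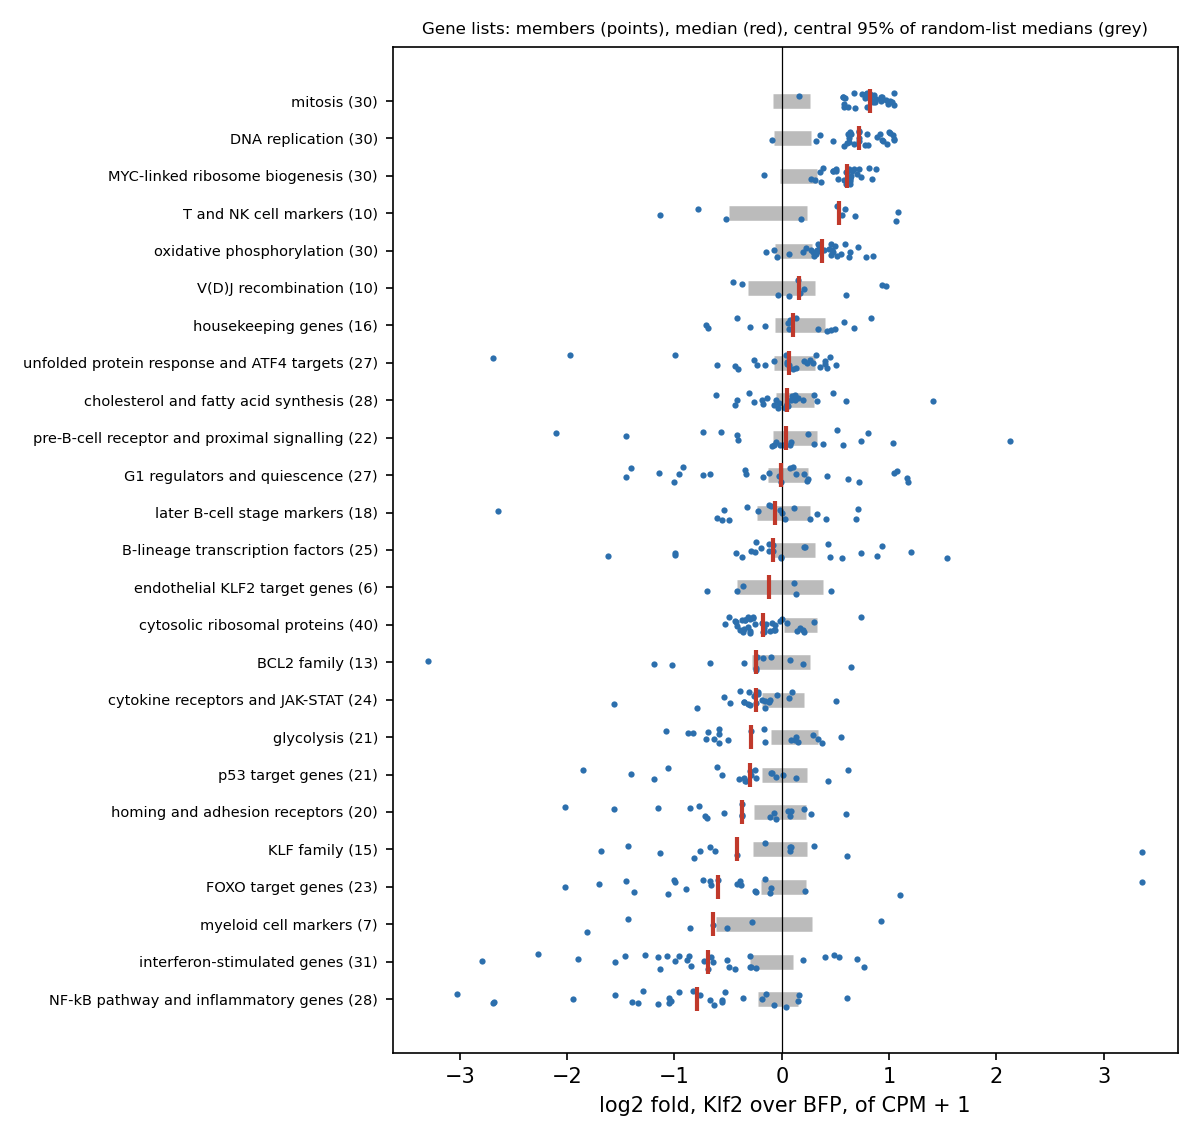
Log2 difference of CPM + 1, Klf2 over BFP, for the measured members of the 25 gene lists with at least 5 measured genes (points, number in brackets), the median of each list (red) and the central 95% of medians of 10000 random lists matched on expression (grey). Medians run from -0.79 for the NF-kB and inflammatory list to 0.82 for the mitosis list; 5 lists lie above and 10 below the grey range.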

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

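The tests of this part were chosen after the values had been seen. Reads across exon junctions have their own deposited column, which no comparison of genes above uses by itself. They were 31.4-fold higher for Klf2 in the Klf2 library than in the BFP library (20.8 to 49.9), from 694 against 23 reads, more than the 11.1-fold excess of its exon reads. As a share of Klf2 exon reads, junction reads were 20.6% (19.3 to 22.0) in the Klf2 library and 7.32% (4.70 to 10.8) in BFP. Over all genes the share was 22.4% in the Klf2 library and 21.9% in BFP. The share in BFP, from 23 reads, is thus the one far from that of all genes. More transcription of the gene in its own locus would raise intronic reads by a like fold, and Klf2 reads outside exons were instead at a ratio of 0.505 (0.266 to 0.927), 17 reads against 35. Reads outside exons made up 0.503% (0.293 to 0.804) of Klf2 gene reads in the Klf2 library against 10.03% (7.09 to 13.7) in BFP, which is consistent with a spliced or intronless retroviral copy as the source of the excess. The deposited median coverage of Klf2 averaged 0.25 over the Klf2 lanes, against a median of 15.2 for 254 genes within 10% of its RPKM. Of those genes, 5 had a median coverage as low. The Klf2 coding sequence is 1062 bases of an exon length of 1847, so a coding copy covered throughout would not by itself account for the low value. The cause of this low coverage was not tested.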

How the results depend on the processing

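Uniquely placed reads, all gene reads, mean RPKM, centring by GC or expression and scaling on the lowest or highest of 5 expression groups were chosen after seeing the data, and the other settings before. No named gene past the rule and no list outside the random lists turned its direction under any setting that was run for it. The number of higher and lower genes was 432 and 867 with no floor, 121 and 277 with a floor of 10 CPM, 1112 and 1505 at a fold of 1.5, 39 and 103 at a fold of 4, and 146 and 369 on the CPM + 1 scale, where the rule itself sets how many genes can pass. Mean RPKM, with a floor of 1 RPKM in place of 1 CPM and no interval, gave 128 higher and 559 lower, and the cause was not tested. Scaling on the lowest expression group gave 543 and 419, and on the highest 173 and 881, since either moves every gene by the median of that group. Centring by expression gave 331 and 499. The counting interval removed no gene. DESeq2 size factors gave 257 and 632, total counts 205 and 757, GC centring 259 and 560, all gene reads 349 and 675, and uniquely placed reads 249 and 615, of which 224 and 565 were the same genes as in the main result. Leaving out a lane gave 267 to 281 higher and 632 to 654 lower genes. The Klf2 fold was between 10.3 and 11.6 in 10 settings, and 7.79 with a pseudocount of 5, which shrinks folds by construction.

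Of 296 list medians under other settings, 284 stayed on the same side of the edge of the random lists and 12, from 6 lists, crossed it. These were the homing list (floor of 10 CPM, pseudocount of 5, mean RPKM), the interferon-stimulated list (floor of 10 CPM), the KLF list (without lane 3, pseudocount of 5), the myeloid list (without lane 2 or lane 3, pseudocount of 5, all gene reads), and the BCL2 (without lane 2) and B-lineage transcription factor lists (pseudocount of 5), which came to lie outside. The lists below the random lists numbered 7 to 10 and those above 4 or 5. A further 6 list medians near 0 changed sign under some setting. Of the folds of named genes, 1028 stayed within the counting interval and 171 did not, with a pseudocount of 5 more often than in any other setting. No paired analysis was possible because lanes of a library are not separate samples and no test was fitted. The settings meant for normalized values alone and for separate samples did not apply. Depth limits genes near 1 CPM, and the missing replicates limit every gene.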

Other observations

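Of the tests in this part, the comparison of neighbouring genes with plain shuffles was set before the pairs were counted, though after Ccl3 and Ccl4 had been seen side by side; the others were chosen after their results. Genes past the 2-fold rule lay beside each other on the chromosomes more often than shuffled genes. Counting neighbours in the order of tested genes that do not overlap and have at least 90% uniquely placed reads, 49 of 6450 pairs held 2 genes of the same direction, 40 lower and 9 higher. None of 10000 shuffles reached 49 (mean 24.6, highest 44), and 0 of 10000 shuffles within 20 bins of expression did (mean 21.8, highest 41). Neither direction alone lay beyond all plain shuffles, which reached 40 lower and 12 higher pairs at most. Lower pairs included Ccl3 and Ccl4, Oas2 and Oas3, Oasl2 and Oasl1, and Ms4a6b and Ms4a6d. They also included Pigr and Faim3 (-1.76 and -2.79), Ypel5 and Lbh (-1.59 and -1.61) and Klf8 and Sat1 (-1.14 and -1.49). Several pairs are members of 1 gene family, such as Ccl3 and Ccl4. The excess was not counted without such pairs, so it may rest on them. Higher pairs included Tmprss3 and Ubash3a (1.22 and 1.65), Car3 and Car2, and Id3 and E2f2. These pairs were named after their values were seen. Shared regulation of neighbours may account for the excess, and so may reads running past the end of a gene. Neither was tested.

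Reads outside exons, introns of unspliced transcripts among them, moved with the exon reads. Among genes past the rule with at least 50 such reads, 160 of 172 higher genes and 362 of 375 lower genes moved the same way, 95.4% together (93.3 to 97.0), against 68.9% (67.9 to 69.9) of 8606 genes that did not pass. Genes that did not pass have smaller folds, so a lower share among them follows from the rule and does not bear on the cause. The median fold of reads outside exons was 1.87 for the higher and 0.462 for the lower genes. These folds were centred on the median of the genes that did not pass. In data simulated with no intronic difference the share was 52.3%, a value set by how those data were drawn. This is consistent with differences that arise in transcription rather than in mRNA stability alone, with 95.4% as the value that bears on it; unannotated exons could give the same result.

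Whether scaling gave the excess of lower over higher genes stays open, because nothing measured here sets the true scaling of the libraries. The share of lower genes was 69.8% with TMM and 43.6% (40.4 to 46.8) when scaled on the lowest of 5 expression groups, but this follows from moving every gene by a constant, as does the balance reached with a shift of 0.17 on the log2 scale, and neither value is evidence for scaling as the cause. With TMM, 3 other explanations are argued against as the whole cause. Of genes past the rule, 60.1% (56.7 to 63.5) were lower after centring by expression and 68.4% (65.1 to 71.6) after centring by transcript GC. With a floor of 10 CPM, 69.6% (64.8 to 74.1) were lower. All intervals of these shares treat genes as independent, so they may be too narrow. The excess was absent in the highest group, with 32 higher and 26 lower genes, and was 57.5% at a fold of 1.5. A difference in the preparation of the cultures or libraries cannot be told apart from Klf2 with 1 library per group.

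For the lower inflammatory and interferon-stimulated genes, fewer myeloid cells in the Klf2 culture are argued against as the cause: Lyz1, Lyz2, S100a8 and S100a9, abundant in such cells, together stood at 0.386 CPM (0.199 to 0.674) in BFP and 0.669 CPM in Klf2, and each of the 28 lower genes lost more (0.913 to 406 CPM, median 17.8 in the inflammatory and 2.97 in the interferon-stimulated list). Fcgr1 and Tyrobp were lower in Klf2 and the myeloid list had a median of -0.64, at the 1.79 percentile, so a change in cells that lack those 4 transcripts stays open. Low expression is argued against for the inflammatory list, whose median was -0.89 with a floor of 10 CPM and still below the central 95% of matched random lists. It stays open for the interferon-stimulated list, whose median was -0.30 with that floor and inside the random lists. A difference in the activation of the cultures at harvest, or in the response to the retrovirus, remains untested.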
